A study of Caenorhabditis elegans with 9 samples.

How the data were processed

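Whole L4 larvae of C. elegans in lethargus were collected by hand in TRIzol after bleach synchronisation and growth on E. coli OP50, per the labels. RNA was extracted with a lipid tissue kit, and stranded mRNA libraries were sequenced as 75-cycle paired-end reads on a NextSeq500 by IMGM Laboratories, per the labels. There were 9 libraries, 3 biological replicates each of wild type (N2), tm2655 and ok3407, per the labels. The series title writes the last allele as ok4307, while the sample labels write ok3407, which is used here. Per the sheet names and headers of the deposited tables, the authors call tm2655 a loss of function and ok3407 a gain of function. The aligner, read counter, strand setting, genome build and annotation release are not given in the sources used here.

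The deposited gene values are raw counts per library, as unique gene reads, exon reads, intron reads and their total, per the file headers. The authors also deposited RPKM values, reads in exons scaled to exon length and library size. The annotated exon length of each gene is deposited beside the counts in bases. The authors' comparison tables give a p-value and a corrected p-value per gene from the EDGE test with tagwise dispersions, per the file headers. The same deposited tables give a score, the signed fold change of the EDGE test, negative where the gene was lower in the mutant. Those tables list genes with a corrected p-value under 0.05 and more than a 2-fold change, as checked on their values.

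Total gene reads were analysed, exon and intron reads together, for 46699 genes. Depth was 13.8 M to 40.5 M gene reads per library (M, megareads). The reads carry no molecular identifiers, so intervals and lower bounds describe counting error only. Coordinates are those of the deposited tables. Compared with WBcel235, 44688 gene names matched, 64.4% with identical start and end and 99.63% within 5000 bases.

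Genes were filtered with filterByExpr on the 3 groups, which kept 16055. One edgeR quasi-likelihood model (robust, TMM factors, 1 term per group) was fitted to all 9 libraries, and ok3407 against wild type, tm2655 against wild type and ok3407 against tm2655 were tested with Benjamini-Hochberg adjusted p under 0.05. The labels give no batch and no pairing of replicates. Shares of uniquely mapped reads were taken from the deposited counts. For a gene with 0 reads in a group, the fold is a lower bound against 3 reads over the group, and with 1 to 3 reads it is the ratio of scaled reads with an exact 95% interval. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

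Gene lists, 32 in all, were written from general knowledge before the data were examined, as were the groups, tests, named-gene rule and alternatives other than those named below. Lists with at least 3 tested members were tested with limma camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. Members were counted by the edgeR test over all genes and when adjusted over the list alone. The rule for named genes took nas-38, the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 1 CPM and fully separated groups, 3 members with the smallest p in the direction of each list that camera called, and 10 genes fixed in advance. Genes outside the rule are said to have been chosen after their values were seen.

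Alternatives were RLE factors, total library size, upper quartile factors, no filter, a stricter filter of 5 CPM in 3 libraries, replicate number as a block, the DESeq2 Wald test, limma-trend on log2 RPKM with a pseudocount of 1, fits of the 6 libraries of a comparison alone, and fits that left out each library. Counts adjusted over a list alone were not refitted without each library. Counting exon reads only or uniquely mapped reads only was added after the data were seen. Scripts were tested on simulated data. For ok3407 against wild type edgeR recovered 28.3% of 2-fold and 73.5% of 4-fold changes there, with 6.2% of its calls false. DESeq2 recovered 43% and 88% with 30.4% false. Counts were drawn from the dispersions fitted by edgeR with few changed genes, so these false shares do not carry over to the real data. A simulated list of 20 genes changed 2-fold was called by camera at both correlations and by fry. Of 30 random lists 0 were called by any of these 3 tests. Genes were simulated independently, so this does not show how the tests treat lists of genes that vary together.

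Shared controls were handled by simulating 20 sets of 9 libraries without group differences from the fitted means and dispersions and comparing the correlation and covariance of the 2 alleles' changes with theirs. For the closing tests, the first 2 principal components of the differences within wild type and within tm2655 were removed from all libraries. Isoforms, sequence variants and reads outside annotated genes were left out because the deposited tables hold values per gene only.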

Results

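Gene expression was measured by RNA sequencing in whole C. elegans larvae that were picked by hand while they slept in L4 lethargus, the quiet phase before the last molt. The gene under study, nas-38, encodes a secreted metalloprotease of the astacin family. Wild type animals (strain N2) were compared with animals of 2 nas-38 alleles, tm2655 (strain HBR1114) and ok3407 (strain HBR1010), with 3 libraries in each group. Gene reads, in megareads (M), numbered 13.8 M, 32.9 M and 24.3 M in the wild type libraries, 28.1 M, 31.5 M and 31.4 M in tm2655, and 26.1 M, 30.6 M and 40.5 M in ok3407. The p-values of single genes rest on the 3 biological replicates per condition that the labels state, and 16055 genes were tested. Camera p-values at the preset correlation compare the genes of a list with the other genes. They depend on the spread between genes and on that assumed correlation, so small values are not evidence from the replicates alone. With an estimated correlation camera called 0 lists in each comparison. Levels are CPM, the counts of a gene scaled to a common library size (mean ± SD, n = 3 libraries). Changes are log2 fold changes from the edgeR quasi-likelihood fit with Benjamini-Hochberg adjusted p-values. The ± value beside a change is an approximate standard error, the absolute change divided by the square root of the F statistic. Counting intervals and lower bounds given for rarely detected genes cover counting error only, because the reads carry no molecular identifiers. The first principal component took 38.76% of the variance and placed the ok3407 libraries at -67.1 to -47, and the wild type libraries and tm2655 replicates 2 and 3 at 26.8 to 51.3. tm2655 replicate 1 stood between them, at -1.33, and apart from all other libraries on principal component 3 (66.1, others -20.1 to 5.32).

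The first comparison, ok3407 against wild type, asked which transcripts go with an allele that the deposited tables call a gain of function. The transcript of nas-38 itself (chromosome X, 558190 to 563629) stood at 313 ± 77.1 CPM in ok3407 and 85.7 ± 42.0 in wild type. It rose by 1.87 ± 0.37 (3.66-fold, adjusted p = 0.0265), with all 3 ok3407 libraries above all 3 wild type libraries. The call was lost without wild type replicate 2 (1.64, adjusted p = 0.0563), wild type replicate 3 (1.71, 0.115), ok3407 replicate 2 (1.7, 0.0929) or ok3407 replicate 3 (1.82, 0.0556).

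Most of the tested antimicrobial peptide genes of the epidermis rose in ok3407. nlp-29 (chromosome V, 3984447 to 3984737), a peptide gene that fungal infection and wounding induce in the skin, stood at 337 ± 139 CPM in ok3407 and 30.2 ± 15.4 in wild type (3.49 ± 0.75, adjusted p = 0.0355). Its neighbour nlp-34 (chromosome V, 3978903 to 3979128) rose from 13.8 ± 8.20 to 165 ± 41 CPM (3.60 ± 0.42, adjusted p = 0.00428). nlp-31 rose by 3.05 ± 0.37 (adjusted p = 0.0049), nlp-30 by 3.07 ± 0.50 (0.0155) and nlp-25 by 2.23 ± 0.39 (0.018). The caenacin cnc-2 (chromosome V, 1449791 to 1450174), which also encodes an epidermal antimicrobial peptide, went from 2.24 ± 1.65 to 91.4 ± 38 CPM (5.46 ± 0.64, 44.1-fold, adjusted p = 0.00491). cnc-10 rose by 2.44 ± 0.38 (adjusted p = 0.0107) and cnc-9 by 7.21 ± 1.03 (0.00855). cnc-1 had 0 reads in wild type and 393 in ok3407, so it was at least 83.6-fold higher (adjusted p = 0.0239), with the bound set at 3 reads over the group. Of the 10 tested nlp peptide genes 7 rose, 0 fell and 3 did not pass, and 7 rose when adjusted over the list alone. Of the 10 tested caenacins 7 rose, 0 fell and 3 did not pass, and 9 rose when adjusted over the list alone. Their median changes were 2.05 for the nlp peptides (camera adjusted p = 1.62e-10) and 4.24 for the caenacins (3.18e-13). With an estimated correlation between genes the adjusted p was 0.30 for the nlp peptides and 0.148 for the caenacins. In fits that left out 1 library, the calls of nlp-31, nlp-34 and cnc-2 were kept each time. Among the 9 peptide genes given here with values, 3 calls were lost without wild type replicate 1 (adjusted p 0.0516 to 0.0733), 1 without wild type replicate 2 (0.0696), 6 without wild type replicate 3 (0.0602 to 0.135), 1 without ok3407 replicate 1 (0.0875) and 3 without ok3407 replicate 2 (0.0571 to 0.0953).

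**Figure D1:**
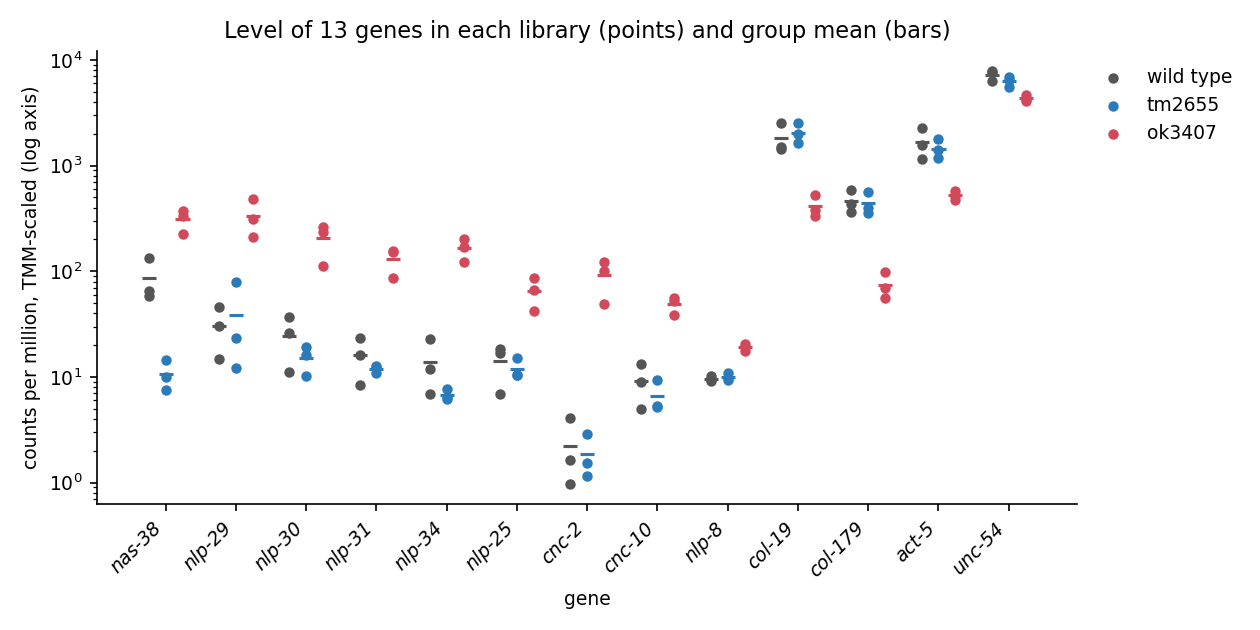
CPM (TMM scaled, log axis) of 13 genes in each library of wild type, tm2655 and ok3407; points are libraries and bars are group means. nlp-34 averaged 165 CPM in ok3407 and 13.8 in wild type, and col-19 averaged 416 and 1820.

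Some genes of the molt and of cuticle remodelling rose in ok3407, while most of those tested did not pass. mlt-3, named for a molting defect (chromosome IV, 12222923 to 12227052), rose from 10.8 ± 2.06 to 59.6 ± 25.7 CPM (2.48 ± 0.37, adjusted p = 0.00959). The kinase gene nekl-2, needed to shed the old cuticle, rose by 1.14 ± 0.21 (adjusted p = 0.0177), and pan-1 rose by 0.63 ± 0.14 (0.0297). Of 39 molting genes 8 rose, 0 fell and 31 did not pass, while 12 rose and 1 fell when adjusted over the list alone (median 0.53, camera adjusted p = 0.000254, adjusted p = 0.841 with an estimated correlation). By library the molting median was 0.16, 0.76 and 0.55 in ok3407 replicates 1, 2 and 3. Of 31 other astacin genes 4 rose, 0 fell and 27 did not pass, and 5 rose when adjusted over the list alone. The list was not called (median 0.09, adjusted p = 0.133). Those 4 were chosen after their values were seen. nas-11 (chromosome X, 6713578 to 6716320) went from 30.2 ± 4.18 to 159 ± 15.6 CPM (2.39 ± 0.19, adjusted p = 0.000707), nas-10 from 1.26 ± 1.56 to 155 ± 80.6 (7.26 ± 1.08, 0.0119), nas-33 rose by 3.87 (0.0265) and nas-9 by 1.72 (0.046). Among 20 epidermis markers outside collagens and peptides, 3 rose, 1 fell and 16 did not pass, and 6 rose and 2 fell when adjusted over the list alone (median 0.02, camera adjusted p = 0.329). The 4 were chosen after their values were seen: the cell fusion genes eff-1 (1.53, adjusted p = 0.00802) and aff-1 (1.77, 0.0393) and the junction gene dlg-1 (0.92, 0.0109) rose, and the GATA factor gene elt-3 fell by 0.92 (0.0391). Hedgehog-related and patched-related genes counted 7 that rose, 1 that fell (grd-6, -1.78, adjusted p = 0.0322, chosen after its value was seen) and 64 that did not pass of 72. When adjusted over the list alone 9 rose and 3 fell, and the list was not called (median 0.26, adjusted p = 0.104). Of 12 genes given here with values from these 4 groups of genes, nas-11 and eff-1 kept their calls whichever library was left out, and nas-9 and aff-1 lost theirs in each fit. Calls were lost for 7 without wild type replicate 1 (adjusted p 0.0583 to 0.0891), 5 without wild type replicate 2 (0.0624 to 0.096), 10 without wild type replicate 3 (0.0613 to 0.163), 5 without ok3407 replicate 1 (0.0609 to 0.104), 7 without ok3407 replicate 2 (0.062 to 0.119) and 2 without ok3407 replicate 3 (0.0909 to 0.0955).

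Some cuticle collagen, muscle and intestinal genes fell in ok3407, while most of those tested did not pass. col-19 (chromosome X, 421724 to 422646), a collagen of the adult cuticle, stood at 416 ± 102 CPM in ok3407 and 1820 ± 621 in wild type (-2.13 ± 0.28, adjusted p = 0.00503). col-179 fell by 2.62 ± 0.28 (adjusted p = 0.00246), with 77.8% of its reads uniquely mapped, and col-124 by 2.07 ± 0.25 (0.00364), with 13%. Of 148 collagens 3 rose, 20 fell and 125 did not pass, and 10 rose and 38 fell when adjusted over the list alone (median -0.51, camera adjusted p = 2.46e-07, adjusted p = 0.841 with an estimated correlation). The collagen median differed between ok3407 libraries, at -1.14, -0.29 and 0.024 in replicates 1, 2 and 3, and in refits was -0.22 without ok3407 replicate 1 and -0.10 without wild type replicate 1. The 3 that rose were chosen after their values were seen: col-113 from 248 ± 89.9 to 1111 ± 91.6 CPM (2.17 ± 0.25, adjusted p = 0.00341), col-40 (3.58, 0.0445) and col-183 (4.51, 0.0222). The myosin heavy chain gene unc-54 went from 7274 ± 778 to 4347 ± 275 CPM (-0.74 ± 0.14, adjusted p = 0.0204), and the troponin T genes tnt-2 (-0.89 ± 0.18, 0.0236) and tnt-3 (-0.75 ± 0.14, 0.0181) also fell. All 22 muscle markers had negative values, 10 fell, 0 rose and 12 did not pass, and 14 fell when adjusted over the list alone (median -0.58, camera adjusted p = 1.62e-10, adjusted p = 0.619 with an estimated correlation). The intestinal actin gene act-5 (chromosome III, 13604554 to 13606066) fell from 1668 ± 555 to 525 ± 52.4 CPM (-1.67 ± 0.25, adjusted p = 0.00802), and asp-3 (-0.74, 0.0379) and spl-1 (-0.69, 0.0451) fell too. These were the 3 of 18 intestine markers that fell, with 0 that rose and 15 that did not pass. When adjusted over the list alone 8 fell and 1 rose (median -0.45, camera adjusted p = 2.45e-05, adjusted p = 0.619 with an estimated correlation). All 81 ribosomal protein genes had negative values, of which rpl-41.1 (-2.49, adjusted p = 0.0181) and rpl-41.2 (-1.88, 0.0243) fell, 0 rose and 79 did not pass. The ribosomal list had 2 down when adjusted over the list alone (median -0.31, camera adjusted p = 1.50e-10, adjusted p = 0.841 with an estimated correlation). The mitochondrial stress list had 1 member that fell, the chaperonin gene hsp-60 (-0.69 ± 0.13, adjusted p = 0.0177), 0 that rose and 9 that did not pass. It had 5 down when adjusted over the list alone (median -0.33, camera adjusted p = 0.00794, adjusted p = 0.619 with an estimated correlation). None of the 6 vitellogenins passed by edgeR (2 at unadjusted p under 0.05), and vit-3 fell when adjusted over the list alone (-2.17, chosen after its value was seen). The list was called (median -1.19, camera adjusted p = 0.0222, adjusted p = 0.841 with an estimated correlation), but not without wild type replicate 3 (0.0807) or ok3407 replicate 3 (0.162). Its medians in ok3407 replicates 1, 2 and 3 were -0.24, -1.21 and -2.48. With total library size in place of TMM factors, the medians were -0.28 for collagens, -0.35 for muscle, -0.23 for intestine, -0.08 for ribosomal proteins, -0.11 for mitochondrial stress and -0.94 for vitellogenins, and none of these 6 changed sign. With that scaling 9 of the 81 ribosomal protein genes and 2 of the 22 muscle markers had positive values. Of 15 genes with values from these lower groups, col-19, col-124, col-179, col-113 and act-5 kept their calls whichever library was left out. The number of lost calls was 7 without wild type replicate 1 (adjusted p 0.0511 to 0.102), 3 without wild type replicate 2 (0.0633 to 0.109), 10 without wild type replicate 3 (0.0803 to 0.178), 5 without ok3407 replicate 1 (0.0621 to 0.119), 8 without ok3407 replicate 2 (0.0673 to 0.124) and 2 without ok3407 replicate 3 (0.0612 to 0.0946).

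**Figure D2:**
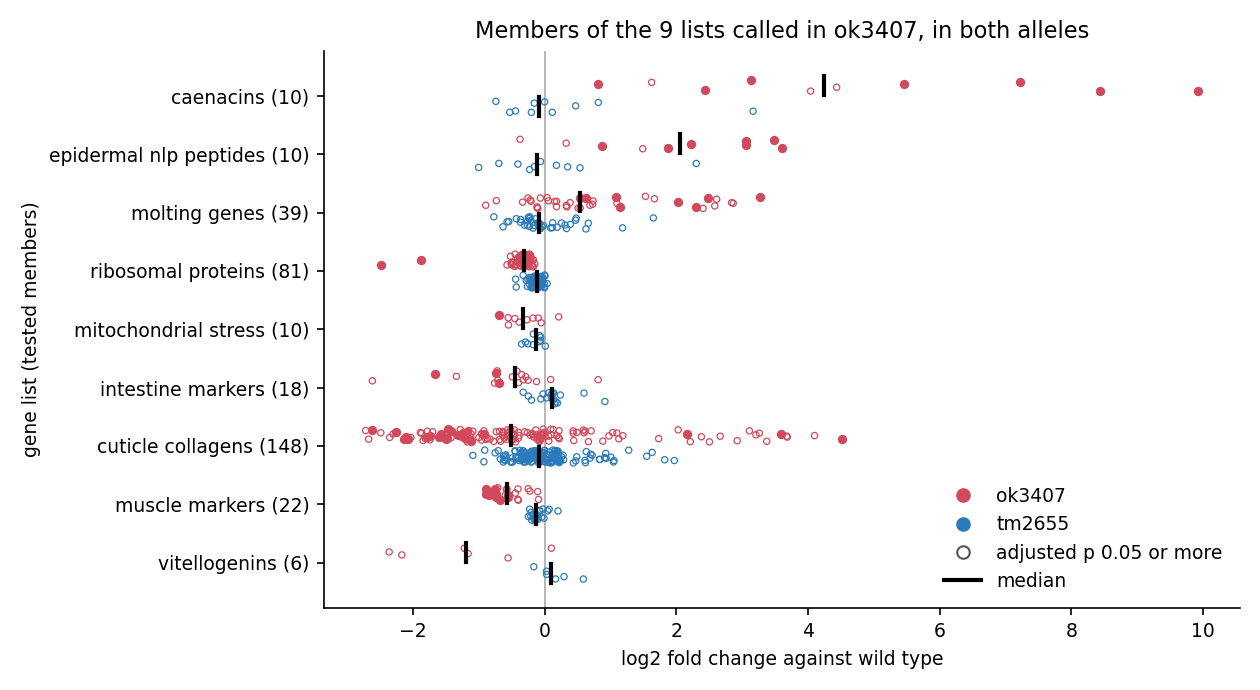
Log2 fold change of each tested member of the 9 lists called in ok3407, in ok3407 and in tm2655 against wild type; filled points passed adjusted p under 0.05 and bars are medians. Genes with 0 reads in a group are drawn at their fitted fold, and the caenacin medians were 4.24 in ok3407 and -0.08 in tm2655.

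Other immune gene groups held members that moved in ok3407, and all genes in this paragraph except ilys-3 were chosen after their values were seen. The fungus-induced peptide gene fip-6 (chromosome I, 8945665 to 8946179) rose from 2.47 ± 1.54 to 132 ± 72.9 CPM (5.81 ± 0.63, adjusted p = 0.00393) and fip-5 rose by 3.75 ± 0.37 (0.0023). The other 20 of 22 family members did not pass, 0 fell, and 3 rose when adjusted over the list alone. The invertebrate lysozyme gene ilys-3 rose from 0.333 ± 0.237 to 54.1 ± 42.7 CPM (7.55 ± 1.12, adjusted p = 0.0118). Of 13 lysozymes ilys-3, ilys-4 (1.14, 0.0307) and lys-10 (4.2, 0.0291) rose, lys-4 fell (-1.54, 0.0472) and 9 did not pass. Their count was 6 up and 5 down when adjusted over the list alone. Of 23 caenopores and antibacterial factors F23F1.7 (1.32, 0.00827) and spp-10 (0.69, 0.00721) rose, 0 fell and 21 did not pass, with 3 up and 2 down when adjusted over the list alone. Of 140 C-type lectin genes clec-40, clec-146, clec-218 and clec-232 rose (2.09 to 5.39), clec-3, clec-56 and clec-210 fell (-2.32 to -1.18) and 133 did not pass. For lectins 2 were up and 1 down when adjusted over the list alone. B0284.1 (5.83, 0.0239) and B0284.2 (6.73, 0.0141) rose among 29 genes of the intracellular pathogen response, 0 fell and 27 did not pass, with 2 up when adjusted over the list alone. For the intestinal PMK-1 effectors F35E12.5 rose (5.03, adjusted p = 0.0434), C17H12.8 (-2.28, 0.0237) and F55G11.8 (-0.97, 0.0264) fell and 12 did not pass. In that list 2 were up and 5 down when adjusted over the list alone. For 32 regulators of the epidermal immune response tir-1 (0.76, 0.0275), an adaptor gene upstream of PMK-1, and the Smad gene sma-3 (0.73, 0.0436) rose, elt-3 fell and 29 did not pass. Here 9 were up and 2 down when adjusted over the list alone. These 6 genes were chosen after their values were seen. No member of 18 chitinase-like genes passed by edgeR (1 at unadjusted p under 0.05), and 0 passed when adjusted over the list alone. None of these 8 immune lists was called by camera, with medians of 0.25 for fungus-induced genes, 0.48 for lysozymes, -0.02 for caenopores, -0.09 for C-type lectins, 0.31 for the intracellular pathogen response, -0.51 for PMK-1 effectors, 0.07 for epidermal regulators and 0.02 for chitinase-like genes. The medians of caenopores (0.19) and C-type lectins (0.12) were positive with total library size, and for both the mean was positive and the test pointed down. Of 22 genes in these immune groups fip-5, fip-6 and spp-10 kept their calls whichever library was left out, and lys-4 and clec-3 lost theirs in each fit. Lost calls numbered 14 without wild type replicate 1 (adjusted p 0.0672 to 0.136), 10 without wild type replicate 2 (0.0505 to 0.0983), 18 without wild type replicate 3 (0.0558 to 0.172), 13 without ok3407 replicate 1 (0.0534 to 0.111), 13 without ok3407 replicate 2 (0.0658 to 0.149) and 8 without ok3407 replicate 3 (0.0579 to 0.11).

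Among genes that act in sleep, the neuropeptide gene nlp-8 (chromosome I, 7800764 to 7801808) rose from 9.65 ± 0.501 to 19.1 ± 1.53 CPM (0.98 ± 0.15, adjusted p = 0.00945). let-23, the receptor gene of epidermal growth factor, rose by 0.95 ± 0.19 (adjusted p = 0.0243) and was chosen after its value was seen. The other 27 of 29 sleep genes did not pass, 0 fell, and 2 rose when adjusted over the list alone. flp-11, a peptide gene of a sleep-active neuron, had 11 CPM in ok3407 and 9.13 in wild type (0.29 ± 0.17, adjusted p = 0.347), npr-12 had a change of 0.77 ± 0.24 (0.0946) and nas-37 of 1.1 ± 0.50 (0.22). Of the neuropeptide genes 6 rose, 1 fell (ins-33, -2.59 ± 0.38, adjusted p = 0.00746, chosen after its value was seen) and 112 did not pass, with the same numbers when adjusted over the list alone. Of 24 neuron markers the glutamate transporter gene eat-4 fell (-1.26, adjusted p = 0.0324, 65.5% of reads uniquely mapped, chosen after its value was seen), 0 rose and 23 did not pass, with 1 that fell when adjusted over the list alone. Medians were -0.02 for sleep genes, -0.02 for neuropeptides and 0.05 for neuron markers, opposite in sign to the mean in each, and those of sleep genes (0.18) and neuropeptides (0.20) were positive with total library size. Stress genes fixed in advance did not pass: the endoplasmic reticulum chaperone gene hsp-4 (-0.16 ± 0.34, adjusted p = 0.818, positive at 0.03 with total library size), gpdh-1 of the osmotic response (0.48 ± 0.69, 0.72) and gst-4 of the oxidative response (0.37 ± 0.32, 0.526). Of 26 endoplasmic reticulum stress genes dnj-27 rose (1.11, adjusted p = 0.046), 0 fell and 25 did not pass, and 0 passed when adjusted over the list alone. Of 23 targets of DAF-16 the lipase gene lips-17 (1.18, 0.0104) and the ferritin gene ftn-1 (2.52, 0.0446) rose, 0 fell and 21 did not pass, with 3 up and 3 down when adjusted over the list alone. Of 171 cytochrome P450, glucuronosyltransferase and glutathione transferase genes cyp-13A10 (2.37), cyp-32A1 (1.74, adjusted p = 0.00158), ugt-33 (3.79) and ugt-51 (1.80) rose, 12 fell and 155 did not pass. Detoxification genes counted 11 up and 15 down when adjusted over the list alone. Of 76 sperm markers nspd-11, of a nematode-specific peptide family, rose (3.65, adjusted p = 0.0335), 0 fell and 75 did not pass, with 0 when adjusted over the list alone. dnj-27, lips-17, ftn-1, these 4 detoxification genes and nspd-11 were chosen after their values were seen. Calls among nlp-8, let-23, ins-33, eat-4 and those 8 genes, 12 in all, were lost for 7 without wild type replicate 1 (adjusted p 0.0682 to 0.132), 7 without wild type replicate 2 (0.0508 to 0.106) and 10 without wild type replicate 3 (0.059 to 0.172). They were lost for 7 without ok3407 replicate 1 (0.0556 to 0.125), 7 without ok3407 replicate 2 (0.0746 to 0.142) and 2 without ok3407 replicate 3 (0.0618 to 0.0713), were lost in each fit for ugt-51 and were kept in each for ins-33 and cyp-32A1.

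No member passed by edgeR among 16 heat shock genes (median 1.55, 5 at unadjusted p under 0.05), 11 osmotic stress genes (0.34, 1), 28 germ line markers (-0.07, 2), 56 histone genes (0.46, 10) and 18 developmental timing genes (-0.06, 2). None passed when adjusted over each list alone. The heat shock median was -0.11 with a stricter filter and -0.23 with uniquely mapped reads, and the histone median was -0.09 and -0.12. With total library size the medians of the germ line (0.14), sperm (0.03) and developmental timing (0.16) were positive. The medians of endoplasmic reticulum stress genes (-0.21), DAF-16 targets (0.16), detoxification genes (0.14) and sperm markers (-0.19) belonged to lists that camera did not call. For the detoxification list the median and mean were positive and the test pointed down, and for developmental timing the mean was positive while the median and the test were negative.

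The transcripts with the largest folds included unnamed genes. Y39A3B.7 had 0 reads in wild type and 450 in ok3407, at least 95.7-fold higher, and R13D11.10 had 0 and 395, at least 84.0-fold higher with 89.4% of its reads uniquely mapped. The sodium-proton exchanger gene nhx-6 had 2 and 650 reads, a ratio of 207 (95% counting interval 57.2 to 1716), C18D11.6 had 1 and 362 (231, 41 to 9150) and F21H7.12 had 1 and 289 (184, 32.8 to 7310). C50F7.5 stood at 115 ± 121 CPM in ok3407 and 0.781 ± 0.346 in wild type (7.31 ± 1.76, adjusted p = 0.0483). The largest falls were those of ZK218.11 (-8.17 ± 1.78, adjusted p = 0.0365), ZK218.5 (-7.83 ± 1.61, 0.0308), ZK218.7 (-5.89 ± 1.11, 0.0238), nspb-3 (-5.43, 0.0355, 81% of reads uniquely mapped), T20D4.3 (-4.42, 0.0187), D1022.3 (-4.13, 0.0239), nspb-1 (-3.60, 0.0357, 67.8% uniquely mapped) and T20D4.5 (-3.41, 0.0497). C50F7.5, nspb-3 and ZK218.11 lost their calls in each fit without 1 library. All 14 calls were lost without wild type replicate 3 (adjusted p 0.0613 to 0.169), 7 without wild type replicate 1 (0.0551 to 0.126), 9 without wild type replicate 2 (0.0502 to 0.103), 7 without ok3407 replicate 1 (0.0519 to 0.129), 11 without ok3407 replicate 2 (0.0652 to 0.145) and 6 without ok3407 replicate 3 (0.0562 to 0.101).

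In all, 1001 of 16055 genes passed, 534 higher and 467 lower in ok3407 (53.3% higher), and 587 of them changed more than 2-fold. With total library size 757 were higher and 167 lower (81.9% higher, median of all genes 0.24), and with limma on RPKM 730 and 223 (76.6% higher, median 0.17), against a median of 0.03 with TMM factors. The 2 groups of libraries were fully separated for 4630 genes, 28.8% of those tested, where chance gives 10%. The count was 123 without wild type replicate 3 (77.2% higher) and 299 without ok3407 replicate 2 (70.6%). It was 385 without wild type replicate 1 (68.3%), 521 without ok3407 replicate 1 (70.4%) and 815 without ok3407 replicate 3 (56.7%). Without wild type replicate 2 it was 905, with 445 higher and 460 lower (49.2% higher). DESeq2 called 2033, 986 higher and 1047 lower (48.5% higher), among them all 1001. In simulated data with few changed genes 30.4% of its calls were false against 6.2% for edgeR. These shares do not carry over to the real calls. The authors listed 925 genes for this allele, 647 higher and 278 lower, of which 884 were tested here, 881 had the same direction and 537 passed.

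The second comparison, tm2655 against wild type, asked the same of the allele that the deposited tables call a loss of function. nas-38 stood at 10.7 ± 3.45 CPM in tm2655 and 85.7 ± 42.0 in wild type, a change of -3.0 ± 0.39 (8.02-fold) with every tm2655 library below every wild type library. It did not pass with edgeR (p = 3.94e-05, adjusted p = 0.316), while the authors' table gives a corrected p of 5.92e-12 and DESeq2 an adjusted p of 2.47e-12. Counts per gene do not separate a lower transcript level from reads missing in an altered part of the gene. The calmodulin-related gene cal-6 (chromosome X, 139221 to 139640) rose, with 73, 94 and 95 reads in tm2655, 0, 1 and 0 in wild type and 3, 2 and 3 in ok3407. The ratio of 262 reads to 1 was 202 (95% counting interval 35.9 to 7999, adjusted p = 0.00825). The call was lost without tm2655 replicate 2 (0.0835), tm2655 replicate 3 (0.0671), wild type replicate 1 (0.0642), wild type replicate 2 (0.148) or wild type replicate 3 (0.0764), and with replicate number as a block (0.123) or exon reads only (0.228).

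The peptide genes that rose in ok3407 did not pass in tm2655, which does not show that they were unchanged. nlp-29 stood at 38.3 ± 35.9 CPM in tm2655 (0.35 ± 0.69) and cnc-2 at 1.86 (-0.16 ± 0.61). Both signs turned in some fits, with nlp-29 at -0.75 without tm2655 replicate 1 and cnc-2 at 0.54 without wild type replicate 1. The changes of nlp-25 (-0.23), nlp-8 (0.06 ± 0.15), flp-11 (0.05), npr-12 (0.21), nas-37 (0.47), hsp-4 (-0.58 ± 0.34), gpdh-1 (0.76 ± 0.69) and gst-4 (0.19) did not pass either (edgeR adjusted p = 0.998 for all 10 genes). cal-6 was the only gene of 16055 that passed, 397 had an unadjusted p under 0.05, and 1038 (6.5%) were fully separated where chance gives 10%. DESeq2 called 4 genes. Its false share of 25.9% in simulated data with few changed genes does not carry over to these calls. In the simulation edgeR found 20% of 2-fold changes and 71.9% of 4-fold changes in this comparison. The authors listed 7 genes, nas-38, cal-6, Y39G8B.7, pud-1.1, T10B5.8, F23D12.11 and F37H8.3, all with the same direction here.

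Camera called 12 lists in tm2655 although 0 of their members passed the edgeR test over all genes and 1 passed when adjusted over the list alone, the lysozyme gene lys-10 (3.57 ± 0.91, higher, chosen after its value was seen). Higher were fungus-induced genes (median 0.36, adjusted p = 0.00113, 0.764 with an estimated correlation), lysozymes (0.60, 2.92e-06, 0.171), C-type lectins (0.22, 0.0003, 0.526), the intracellular pathogen response (0.45, 0.00936, 0.764, median -0.005 with a stricter filter), chitinase-like genes (0.59, 0.0494, 0.526), detoxification genes (0.18, 0.0003, 0.764) and DAF-16 targets (0.43, 0.0003, 0.526). Lower were muscle markers (-0.12, 0.0162, 0.964), sperm markers (-0.13, 0.00117, 0.964), endoplasmic reticulum stress genes (-0.22, 2.92e-06, 0.764), mitochondrial stress genes (-0.13, 0.005, 0.526) and ribosomal proteins (-0.11, 2.92e-06, 0.964). With an estimated correlation 0 lists were called (2 at unadjusted p under 0.05), and fry called 0 (3 at unadjusted p under 0.05). The nlp peptides (median -0.11, mean 0.08) and caenacins (median -0.08, -0.29 with bounds for genes with 0 reads, mean 0.25) were not called. Leaving out tm2655 replicate 1 ended the calls of fungus-induced genes (0.179), the intracellular pathogen response (0.628), muscle (0.907) and sperm (0.961), tm2655 replicate 2 those of muscle (0.0626) and chitinase-like genes (0.058), and tm2655 replicate 3 those of fungus-induced genes (0.0728), chitinase-like genes (0.162) and DAF-16 targets (0.138). Without wild type replicate 1 the calls of fungus-induced genes (0.0616) and muscle (0.164) were lost, and the sperm median was 0.07. Calls were lost without wild type replicate 2 for fungus-induced genes (0.0681), chitinase-like genes (0.11), C-type lectins (0.30) and mitochondrial stress (0.0632), and without wild type replicate 3 for the intracellular pathogen response (0.211), muscle (0.546), chitinase-like genes (0.119) and ribosomal proteins (0.17). Lysozymes, detoxification genes and endoplasmic reticulum stress genes were called in each of these 6 fits.

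The third comparison set the alleles against each other, ok3407 against tm2655, and so tested their difference without the wild type libraries in the contrast. nas-38 was 29.3-fold higher in ok3407 (4.87 ± 0.42, adjusted p = 0.00113), and that call was kept whichever library was left out (4.68 to 5.15). Most epidermal peptide genes were again higher: nlp-34 stood at 165 ± 41 against 6.79 ± 0.770 CPM (4.6 ± 0.44, adjusted p = 0.00192), nlp-31 rose by 3.46 (0.00285), nlp-30 by 3.76 (0.00791), nlp-25 by 2.45 (0.0127), cnc-2 by 5.62 ± 0.63 (0.00402), cnc-9 by 7.95 (0.00559) and cnc-10 by 2.88 (0.00503). nlp-29 did not pass (3.14 ± 0.74, adjusted p = 0.0573). Of 10 nlp peptides 6 rose, 0 fell and 4 did not pass, with 7 up when adjusted over the list alone (median 2.20, camera adjusted p = 3.63e-12, adjusted p = 0.241 with an estimated correlation). Of 10 caenacins 6 rose, 0 fell and 4 did not pass, with 9 up when adjusted over the list alone (median 3.64, 2.36e-17, adjusted p = 0.0728 with an estimated correlation). A few astacin, molting and epidermis genes differed between the alleles too. nas-11 stood at 159 ± 15.6 CPM in ok3407 and 32.9 ± 8.15 in tm2655 (2.27 ± 0.19, adjusted p = 0.000595), nas-10 (chromosome X, 10960982 to 10964725) at 155 ± 80.6 and 0.264 ± 0.228 (9.19 ± 1.19, 0.00661), and nas-33 was higher by 3.93 (0.0274). Of 31 astacins these 3 rose, 0 fell and 28 did not pass, with 4 up and 1 down when adjusted over the list alone (median 0.21, camera adjusted p = 0.0458, adjusted p = 0.706 with an estimated correlation). mlt-3 (2.50, adjusted p = 0.00791), nekl-2 (1.25, 0.0122), the protease gene cpl-1 (1.05, 0.0186) and the oxidase gene bli-3 (0.61, 0.0233, chosen after its value was seen) rose among 39 molting genes, 0 fell and 35 did not pass. Molting genes had 8 up when adjusted over the list alone (median 0.61, 5.46e-06, adjusted p = 0.583 with an estimated correlation). Of 72 hedgehog-related and patched-related genes ptr-1 (3.19, adjusted p = 0.00874), ptr-8 (1.33, 0.0184), grl-4 (1.26, 0.0183), grl-31 (3.77) and grl-14 (2.72) rose, the last 2 chosen after their values were seen, 0 fell and 67 did not pass. This list had 7 up and 1 down when adjusted over the list alone (median 0.33, 0.0287, adjusted p = 0.747 with an estimated correlation). Of 20 epidermis markers eff-1 (1.79, adjusted p = 0.00393), aff-1 (2.02, 0.0284), dlg-1 (0.82, 0.0159) and ifb-1 (0.64, 0.0363) rose, elt-3 fell by 0.94 (0.0452) and 15 did not pass. Epidermis markers had 7 up and 1 down when adjusted over the list alone (median 0.31, 0.0345, adjusted p = 0.595 with an estimated correlation). ifb-1 and elt-3 were chosen after their values were seen. The astacin list lost its call without tm2655 replicate 1 (0.239), tm2655 replicate 3 (0.0719), ok3407 replicate 2 (0.151) or ok3407 replicate 3 (0.271). The hedgehog and patched list lost it without tm2655 replicate 1 (0.335), tm2655 replicate 3 (0.0631), ok3407 replicate 2 (0.104) or ok3407 replicate 3 (0.408), and so did the epidermis list without tm2655 replicate 1 (0.239), ok3407 replicate 2 (0.0681) or ok3407 replicate 3 (0.112). Of 24 genes with values in these rising groups, nlp-30, nlp-31, nlp-34, cnc-2, cnc-9, cnc-10, mlt-3, nas-10, nas-11, ptr-1 and eff-1 kept their calls in each fit, and ifb-1 lost its call in each. Lost calls numbered 8 without tm2655 replicate 1 (adjusted p 0.0535 to 0.0881), 11 without tm2655 replicate 2 (0.0523 to 0.12), 13 without tm2655 replicate 3 (0.0636 to 0.164), 2 without ok3407 replicate 1 (0.102 to 0.119), 10 without ok3407 replicate 2 (0.0539 to 0.146) and 4 without ok3407 replicate 3 (0.0502 to 0.0682).

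Some collagen, muscle and intestinal genes were lower in ok3407 than in tm2655, while most did not pass. col-19 stood at 416 ± 102 and 2055 ± 468 CPM (-2.31 ± 0.28, adjusted p = 0.00345), col-179 fell by 2.55 (0.00226) and col-124 by 2.31 (0.00213, 13% of reads uniquely mapped). Of 148 collagens 18 fell, 125 did not pass and 5 rose, namely col-40 (3.71), col-109 (1.68), col-113 (2.62), col-182 (2.64) and col-183 (4.71), chosen after their values were seen. As a list, collagens had 7 up and 34 down when adjusted over the list alone (median -0.28, camera adjusted p = 6.96e-07, adjusted p = 0.706 with an estimated correlation). Of 22 muscle markers tnt-3 fell (-0.82, adjusted p = 0.0134), 0 rose and 21 did not pass, with 14 down when adjusted over the list alone (median -0.46, 6.40e-08, adjusted p = 0.583 with an estimated correlation). Of 18 intestine markers act-5 (-1.47, adjusted p = 0.0121), the intermediate filament gene ifd-2 (-0.88, 0.0452) and spl-1 (-0.72, 0.048) fell, 0 rose and 15 did not pass. Intestine markers had 11 down when adjusted over the list alone (median -0.72, 6.96e-07, adjusted p = 0.422 with an estimated correlation). None of 6 vitellogenins passed by edgeR (2 at unadjusted p under 0.05). vit-3 (-2.0) and vit-4 (-2.53) fell when adjusted over the list alone and were chosen after their values were seen (list median -1.35, 0.00299, adjusted p = 0.583 with an estimated correlation). The vitellogenin median was -2.09 without ok3407 replicate 1 and -1.02 without ok3407 replicate 3. With total library size the medians were -0.099 for collagens, -0.28 for muscle, -0.55 for intestine, -1.18 for vitellogenins, -0.091 for C-type lectins and -0.029 for ribosomal proteins, of which 31 of 81 were then positive. Of 140 C-type lectins clec-56, clec-66, clec-210 and clec-227 fell, clec-232 rose and 135 did not pass, with 1 up and 4 down when adjusted over the list alone (median -0.26, camera adjusted p = 0.00982, adjusted p = 0.583 with an estimated correlation). clec-66 and clec-232 were chosen after their values were seen, as were the 2 detoxification genes that rose, cyp-13A10 (2.56) and cyp-32A1 (1.42). In that list of 171 genes 9 fell, among them ugt-12 (-1.64, adjusted p = 0.00624), ugt-46 (-1.37, 0.00682) and ugt-64 (-0.91, 0.0114), and 160 did not pass, with 2 up and 13 down when adjusted over the list alone. Its median of -0.09 (0.0458, adjusted p = 0.747 with an estimated correlation) was 0.08 with total library size, and its call was lost without tm2655 replicate 1 (0.245), ok3407 replicate 1 (0.273) or ok3407 replicate 3 (0.229). Of 81 ribosomal proteins rpl-41.1 (-2.05) and rpl-41.2 (-1.60) fell, 0 rose and 79 did not pass, with 0 when adjusted over the list alone (median -0.20, 1.26e-05, adjusted p = 0.747 with an estimated correlation). Of 24 genes with values in these falling groups col-19, col-124, col-179, col-113, act-5, ugt-12, ugt-46, ugt-64 and cyp-32A1 kept their calls in each fit, and rpl-41.1 lost its call in each. Calls were lost for 10 without tm2655 replicate 1 (adjusted p 0.0502 to 0.114), 11 without tm2655 replicate 2 (0.0578 to 0.155), 12 without tm2655 replicate 3 (0.0528 to 0.175), 5 without ok3407 replicate 1 (0.078 to 0.122), 11 without ok3407 replicate 2 (0.0526 to 0.159) and 6 without ok3407 replicate 3 (0.0567 to 0.0954).

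Large single differences between the alleles included F32G8.3 (6.41, adjusted p = 0.00111) and fip-6 (6.02, 0.00293). R13D11.10 had 0 reads in tm2655 and 395 in ok3407, at least 109-fold higher. The read ratio was 109 for cnc-1 (3 and 393 reads, 95% counting interval 36.9 to 529), 539 for nhx-6 (1 and 650, 96.3 to 21309) and 150 for C18D11.6 (2 and 362, 41 to 1243). Lower in ok3407 were cal-6 (-5.21 ± 0.48, adjusted p = 0.000915), T20D4.3 (-5.37, 0.00877), nspb-3 (-5.23, 0.0478), ZK218.7 (-4.89, 0.0457), T20D4.5 (-4.68, 0.0211), D1022.3 (-4.41, 0.0202), nspb-1 (-3.79) and Y45G12C.4 (-3.69, 0.0238, 1.9% of reads uniquely mapped). Of 16 genes with large differences, nas-10 and cnc-9 included, 7 kept their calls in each fit, and calls were lost for 2 without tm2655 replicate 1 (adjusted p 0.0514 to 0.076), 8 without tm2655 replicate 2 (0.0576 to 0.112), 8 without tm2655 replicate 3 (0.061 to 0.14), 4 without ok3407 replicate 1 (0.0659 to 0.117), 6 without ok3407 replicate 2 (0.0527 to 0.169) and 3 without ok3407 replicate 3 (0.073 to 0.118). The smaller rise of nlp-8 (0.92 ± 0.15, adjusted p = 0.0109) was kept in each fit, while flp-11 (0.24), npr-12 (0.56), nas-37 (0.63), hsp-4 (0.42), gpdh-1 (-0.27) and gst-4 (0.18) did not pass.

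Between the alleles 645 genes passed, 374 higher and 271 lower in ok3407 (58% higher), and 3763 (23.4%) were fully separated where chance gives 10%. With total library size 464 were higher and 139 lower (76.9% higher, median of all genes 0.19), and with limma on RPKM 443 and 169 (72.4% higher, median 0.12). DESeq2 called 1471, 712 higher and 759 lower (48.4% higher), and edgeR on the 6 libraries alone 390, so the share that was higher depended on the method. The count was 222 without tm2655 replicate 3 (67.6% higher), 280 without tm2655 replicate 2 (67.5%) and 288 without ok3407 replicate 2 (69.8%). The other fits without 1 library had 54.4% to 70.4% higher, so the share also depended on the libraries used. Camera called 13 of 32 lists, against 0 with an estimated correlation (3 at unadjusted p under 0.05) and 4 by fry, the nlp peptides, caenacins and epidermal immune regulators (higher) and intestine markers (lower). In ok3407 against wild type camera called 9, against 0 with an estimated correlation (2 at unadjusted p under 0.05) and 6 by fry, those 4 with muscle markers and the mitochondrial stress list (both lower).

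Both alleles share their 3 wild type libraries, so their changes against wild type were compared with simulated groups without change that share controls in the same way. Across 16055 genes, which are not independent replicates, the changes correlated with r = 0.46 (Spearman 0.42), against a mean of 0.52 (0.48 to 0.54) in 20 simulations. The covariance was 0.184, against 0.0941 (0.0844 to 0.103). It was 0.0977 without tm2655 replicate 1, within that range, 0.374 without wild type replicate 1, 0.382 without wild type replicate 2 and 0.0735 with the stricter filter. The simulations were not repeated for these settings, so a change shared by the alleles was not shown. No gene was called by edgeR in both alleles, since tm2655 had 1 call that ok3407 lacked, where 0.0333 were expected for independent calls, and 3 controls are too few to give each allele controls of its own. The correlation was 0.24 without tm2655 replicate 1, 0.61 without wild type replicate 1 and 0.61 without wild type replicate 2.

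**Figure D3:**
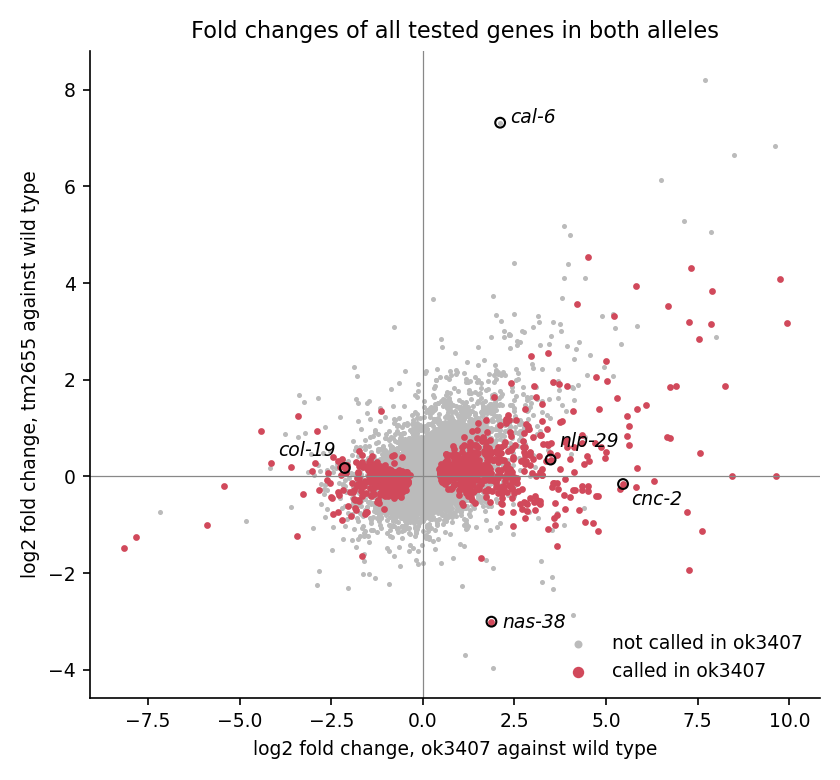
Log2 fold change against wild type of each tested gene in ok3407 (horizontal) and in tm2655 (vertical), as fitted, with genes called in ok3407 in red and 5 genes ringed (cal-6, nlp-29, cnc-2, col-19, nas-38). nas-38 lay at 1.87 in ok3407 and -3.0 in tm2655.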

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

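The tests of multi-mapped reads, of the 3 separate parts of the fall and of genes near nas-38 were chosen after the result was seen. Reads in introns made up 10.6% of gene reads in ok3407 (SD 0.77, n = 3) and 9.13% in wild type (SD 0.267), with each ok3407 library above each wild type library. Intron reads enter the gene counts, and the gene comparisons were not adjusted for this share. An exact two-sided permutation test of the share gave p = 0.1, the smallest that 3 against 3 allows. The share was listed because the groups were fully separated, which fixes this p-value, so the test adds no support. Ribosomal RNA took 1.335% of gene reads in ok3407 replicate 2, against a mean of 0.18% in wild type. Among genes named by the rule, 5 had all libraries of one allele above and all of the other below each wild type library and passed between the alleles with edgeR: nas-38 (4.87, adjusted p = 0.00113), the hedgehog-related gene grl-4 (1.26, 0.0183), the C-type lectin gene clec-227 (-2.63, 0.0146), the glucuronosyltransferase gene ugt-64 (-0.91, 0.0114) and Y45G12C.4 (-3.69, 0.0238, with 1.9% of reads uniquely mapped). Their wild type levels were 85.7, 277, 3.64, 80.7 and 17.1 CPM. The clec-227 call was lost without ok3407 replicate 2 (0.0618), that of grl-4 without tm2655 replicate 1 (0.0538), 2 (0.0629) or 3 (0.0776), and that of Y45G12C.4 without tm2655 replicate 2 (0.066) or 3 (0.0828).

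The rise of the nlp peptides and caenacins in ok3407 was weighed first. A different point of the molt at collection was tested along the axes on which libraries vary within wild type and within tm2655. With the first 2 such components removed, the lowest median of the 20 members in any ok3407 library was 2.04 (SD 0.25), against 2.45 before. That argues against variation along these 2 axes as the whole cause. The 2 components held 40.5% and 28.4% of the variance within groups and took 15.2% of the squared ok3407 difference. Whether they follow the molt was not tested. With them removed the molting list medians in ok3407 replicates 1, 2 and 3 were 0.39, 0.83 and 0.51, against 0.16, 0.76 and 0.55 before. A different point of the molt outside these axes therefore stays open. Reads shared between near-identical copies are argued against, since 0% of the members' 285481 reads mapped to more than 1 place. An effect of the ok3407 allele on the epidermal immune response, and other variants of the 1 strain that carries each allele, stay open and were not tested.

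The fall of collagens, muscle markers and intestine markers in ok3407 was weighed second. For all 188 members together the highest median in any ok3407 library was -0.18 with the components removed (SD 0.25, -0.17 before), which left the molt explanation undecided. By part, variation along the 2 removed components as the whole cause is argued against for muscle (-0.44, SD 0.05, -0.52 before). The intestine (-0.26, SD 0.13, -0.34 before) met the rule of the test only narrowly. A different point of the molt outside these components stays open for both parts. For collagens the medians of ok3407 replicates 1, 2 and 3 were -1.14, -0.29 and 0.024 before and -1.03, -0.198 and -0.077 after (SD 0.52), so collagens were not lower in replicate 3 before removal. For collagens the ok3407 libraries differ too much from each other for the test to decide. An effect of the allele and a different point of the molt cannot be told apart here. Whether the removed components follow the molt was not tested. Scaling between libraries is argued against for all members together, since their median was -0.30 or lower under 4 scalings (lowest -0.56). By part this was not tested, and with total library size each part fell less, without a change of sign. An effect of the allele on these tissues stays open and was not tested.

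The opposite levels of nas-38 in the alleles were weighed last. With the components removed nas-38 stayed at 1.6 or more above wild type in each ok3407 library (1.51 before, SD 0.28). It stayed at -2.75 or lower in each tm2655 library (-2.47 before, SD 0.09). The ok3407 values argue against variation along the 2 removed components as the whole cause in that allele. The components were fitted to the tm2655 libraries themselves, so removing them shrinks the tm2655 spread by construction. The SD of 0.09 is therefore no evidence, and no conclusion is drawn for tm2655. A different point of the molt outside these components stays open for both alleles. A copy number change of the whole stretch within 50 kb of nas-38 in ok3407 is argued against. The median change of the 13 other tested genes there was 0.15 (SD 0.67, -1.26 to 1.13), below the 1.87 of nas-38. Of these 13 genes 1 was called. A gain limited to nas-38 or to a few genes would not move this median and was not tested. An effect of each allele on its own transcript, and other variants of each strain, stay open and were not tested. The counts are sums over the gene. Reads missing from an altered or deleted part of nas-38 could therefore not be told apart from a lower transcript level.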

How the results depend on the processing

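The alternatives that count exon reads only or uniquely mapped reads only were chosen after the result was seen. For genes named by the rule, the direction and the side of the threshold stayed the same in 631 of 768 alternatives for ok3407 against wild type (130 weaker, 2 stronger), 167 of 185 for tm2655 against wild type (7 weaker) and 800 of 938 for ok3407 against tm2655 (128 weaker, 5 stronger). Genes chosen after their values were seen stayed the same in 805 of 1060 (255 weaker) and 414 of 548 (134 weaker) in ok3407 against wild type and against tm2655. Called lists stayed the same in 102 of 117, 110 of 156 and 127 of 169. Fewer libraries lower the power of a fit. Lower power alone would not raise the number of called lists. In ok3407 against wild type that number was 9 with all libraries and 10 to 14 without 1 library. Other causes of the differences below were not tested. For ok3407 against wild type DESeq2 gave 2033 genes, fits without 1 library 123 to 905 genes, 10 to 14 lists and nas-38 at 1.64 to 2.34, and camera with an estimated correlation 0 lists (2 at unadjusted p under 0.05, fry 6). For tm2655 against wild type edgeR gave 0 genes with the stricter filter, which removes cal-6 (236 at unadjusted p under 0.05), 0 with a replicate block (372) and 0 with exon reads (378), against 4 by DESeq2, where nas-38 passed at -3.02. Fits without 1 library gave 0 to 1 gene, 10 to 13 lists and nas-38 at -3.28 to -2.53, and camera with an estimated correlation (2 at unadjusted p under 0.05) and fry (3) gave 0 lists. For ok3407 against tm2655 DESeq2 gave 1471 genes, the 6 libraries alone 390 (273 higher and 117 lower, 70% higher), fits without 1 library 222 to 623 genes, 9 to 14 lists and nas-38 at 4.68 to 5.15, camera with an estimated correlation 0 lists (3 at unadjusted p under 0.05) and fry 4. The correlation of the alleles ran from 0.24 to 0.61 without 1 library.

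These results reversed under an alternative, and for all of these but the sperm list the value had not passed before. The cause was not tested. Medians of called lists that changed sign where camera was not rerun are given above and not counted here. Among them are those of the intracellular pathogen response in tm2655 and of detoxification genes between the alleles. With total library size hsp-4 stood at 0.028 in ok3407 against wild type, with exon reads flp-11 at -0.030 in tm2655 against wild type, and with limma on RPKM cnc-2 at 0.0027 and nlp-29 at -0.056 there. The others reversed without 1 library, and their ranges over those fits follow. In tm2655 against wild type they were -0.0037 to 0.13 for flp-11, -0.60 to 0.54 for cnc-2, -0.75 to 0.77 for nlp-29, -0.064 to 1.22 for gpdh-1, -0.0056 to 0.10 for nlp-8, -0.58 to 0.021 for nlp-25 and -0.24 to 0.069 for the sperm median. In ok3407 against wild type they were -0.60 to 0.092 for hsp-4, -0.36 to 0.95 for gpdh-1 and -0.16 to 0.57 for gst-4. In ok3407 against tm2655 they were -1.12 to 0.55 for gpdh-1, -0.012 to 0.65 for hsp-4 and -0.34 to 0.38 for gst-4.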

Other observations

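The gene families, the position of cal-6 and the genes near nas-38 in this part were chosen after the result was seen. The regroupings of libraries were set before. In ok3407 against wild type 6 of 172 families of genes with a shared name passed a hypergeometric test, whose unit is the gene and which takes members as independent. The report covers members of 3 of them in its lists, cnc (7 of 10 higher, adjusted p = 8.2e-07), nlp (8 of 40 higher, 0.00245) and col (19 of 129 lower, 1.04e-06). The cnc family did not pass without wild type replicate 3 (1), nor did nlp without wild type replicate 2 (0.291), wild type replicate 3 (1) or ok3407 replicate 2 (0.456). Of transthyretin-related genes 12 of 55 tested members were called higher where 1.83 were expected (adjusted p = 1.66e-05). Without wild type replicate 3 the count was 3 of 56 (expected 0.325, adjusted p = 0.745), and without any other library 7 to 12 were called (highest adjusted p 0.00272). ttr-18 went from 77.7 to 526 CPM (2.76), ttr-26 from 14.5 to 216 (3.91), ttr-30 from 14.3 to 108 (2.92) and ttr-51 from 147 to 518 (1.82). Sodium-proton exchanger genes had 4 of 8 members higher (expected 0.27, adjusted p = 0.00327), nhx-1 (1.23), nhx-4 (0.87), nhx-6 and nhx-9 (1.64). The abu genes, which encode repeat proteins of the pharyngeal cuticle, had 4 of 14 members lower (expected 0.41, adjusted p = 0.0482), abu-4 (-2.83, 84.6% of reads uniquely mapped), abu-6 (-1.66, 76.2%), abu-7 (-1.40, 69.2%) and abu-11 (-1.09). All 4 abu calls were lost in each of the 6 fits without 1 library (adjusted p 0.0551 to 0.158), with family adjusted p = 1 in each. The exchanger family passed only without ok3407 replicate 1 (0.0255), and not without ok3407 replicate 2 (0.193) or 3 (0.0508) or wild type replicate 1 (1), 2 (0.537) or 3 (1). Of these 12 genes all lost their edgeR call without wild type replicate 3 (adjusted p 0.0559 to 0.158), 8 without wild type replicate 1 (0.0551 to 0.107), 7 without wild type replicate 2 (0.0537 to 0.0835), 6 without ok3407 replicate 1 (0.0504 to 0.0919), 7 without ok3407 replicate 2 (0.0563 to 0.133) and 5 without ok3407 replicate 3 (0.0775 to 0.104).

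cal-6 lies 419 kb from nas-38 on chromosome X, and 118 tested genes (0.73%) lie as close. The 10 tested genes within 50 kb of cal-6 had changes of -0.30 to 0.68 in tm2655 against wild type, and 0 had an unadjusted p under 0.05 with edgeR. Called genes made up 8.39% of tested genes on chromosome X and 7.53% on chromosome V in ok3407 against wild type, and 4.49% to 5.91% on the other chromosomes. Within 500 kb of nas-38, 5 of 133 tested genes (3.76%) were called in that comparison, col-19 among them, against 6.26% elsewhere. Whether variants near nas-38 changed these genes was not tested.

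The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For ok3407 against wild type the real split called 808 genes (1 split gave as many, highest other 0), and for ok3407 against tm2655 390 (1 split, highest other 1). For tm2655 against wild type the real split called 1 gene and 3 splits gave as many. The highest other, with 15 genes, grouped tm2655 replicates 1 and 2 with wild type replicate 1. Another, with 7 genes, grouped tm2655 replicates 1 and 3 with wild type replicate 3. Both called more genes than the real split, and the cause was not tested. For camera at its preset correlation, the real splits called 10 lists for ok3407 against wild type (6 splits gave as many, highest other 17), 13 for tm2655 against wild type (6 splits, highest other 15) and 14 for ok3407 against tm2655 (3 splits, highest other 17).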
